A study of Mus musculus with 2 samples.

How the data were processed

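The series profiled thymic mimetic cells, which are medullary thymic epithelial cells (mTEC) that take on the expression programs of other tissues. Per the labels, thymi came from 6-week-old female mice of the C57BL/6 (B6), BALB/c and NOD strains. Cells were depleted of CD45-positive leukocytes, sorted as mTEC with low MHC class II that lacked podoplanin (Pdpn) and CD104 (the protein of Itgb4), tagged with 1 hashtag antibody per mouse, pooled, and captured in 1 droplet library (10x Genomics 3' chemistry). The pool held 6 mice, 2 of each strain, and the mouse was the replicate throughout. A hashtag antibody links a droplet to a mouse through a short sequence tag, so hashtag and strain were fixed together by the labels. The title of the hashtag sample writes the same replicate number for both NOD hashtags. They were kept as separate mice because the design text and the other title give 2 mice of each strain.

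The deposited values were UMI counts per gene and per hashtag in each droplet barcode, as whole numbers with no normalization, made by the authors with Cell Ranger 7.0.0 on the mm10 mouse genome per the submitters' processing notes. A UMI count is the number of distinct captured RNA molecules. The annotation release was not given in the sources used here. Of 55487 gene identifiers, 54435 matched GENCODE M21, version number included, and 52647 also had its symbol. Coordinates below are those of M21 on mm10, matched by identifier, and symbols are those of the deposited matrix. The deposited matrix held 3447 barcodes, the lowest with 503 UMIs. It also held 15 hashtag features, of which 6 belonged to this pool and 9 did not.

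Barcodes with at least 500 detected genes and under 15% mitochondrial UMIs were kept (2527 of 3447). Hashtags were called on all barcodes with HTODemux in Seurat 5.3.0 (quantile 0.99, seed 42). Of the passing barcodes, 1575 carried a single hashtag and entered the analysis, 427 were hashtag doublets and 525 had no hashtag called. Scrublet marked 6 of the 2527 passing barcodes (3 of the 1575), so it added almost nothing to the hashtag doublets. Counts were scaled to 10000 per cell and log transformed in scanpy 1.11.5. Highly variable genes were chosen within mice (1986 used of 2000, without mitochondrial, ribosomal, H2- and Xist genes). After 30 principal components and 15 nearest neighbours, Leiden clustering at resolution 1 gave 19 clusters. A cluster was named X-like from fixed marker lists when at least 3 markers were detected in 10% of its cells and lay at least 1 log2 unit above the other cells. These naming thresholds were set after the clusters were seen. Leukocyte-like clusters also needed Ptprc (CD45) in 25% of cells and low keratins. Clusters 2, 8 and 10 passed 5, 4 and 5 of the 7 immature mTEC markers. Because cluster 2 held more pericyte than immature mTEC markers among its 10 leading genes, these clusters are compared by number. Cluster 5 stayed unnamed because it was shallow (median 3821 UMIs against 13774 over all cells) with no marker of that list among its leading genes.

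Cells of each class were counted per mouse and tested with the quasi-likelihood test of edgeR 4.0.16, with all 6 mice in 1 fit and the mouse's cell number as library size. Classes with at least 30 cells were tested (12 tested, 3 given as counts), with Benjamini-Hochberg adjustment over classes. Two-sided exact permutation over 90 arrangements of the strain labels cannot give a p below 0.0667, and 2 mice against 2 cannot go below 0.333. For genes, raw counts were summed over all assigned cells of a mouse and tested with edgeR (TMM, filterByExpr, robust quasi-likelihood, 3 residual degrees of freedom). The fit held 15888 genes, with a common dispersion of 0.0429. Because such sums mix expression with the share of each class, a class-adjusted fit was made with limma 3.58.1 (voom) on 33 sums of at least 10 cells per class and mouse, with class and strain as terms and mouse as block (8124 genes, block correlation -0.0406). The class-adjusted fit held no B6 sum for clusters 2, 5 and 8. Cluster 10 and microfold-, neuroendocrine-, ciliated- and muscle-like cells were left out of it, with sums in a single strain. Its contrasts with B6 thus rest on the other classes, myeloid or dendritic cell-like cells included. The threshold was an adjusted p of 0.05 throughout.

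Lists of genes were fixed before the data were examined: 15 functional lists and 25 cell type marker lists. The ribosomal protein list was taken by symbol, so it also holds pseudogenes and kinase or binding protein genes, which were counted apart after the result was seen. The 36 with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01. On the class-adjusted sums camera was run without the mouse block. Sums of the same mouse counted there as independent, so the camera p-values of that fit may be too small. The fibroblast, mesothelial, parathyroid and erythroid lists had too few tested genes. Genes named from the sums over all cells were chosen by a rule fixed before the data were examined. In each contrast it took the 12 largest changes in each direction among genes that passed the threshold in both fits with the same sign, had both mice of a strain above both of the other, and averaged at least 20 CPM (counts scaled to a common library total). Unnamed gene models were counted but not named. Sizes given for genes named by this rule are those of the sums over all cells unless stated, so they mix expression with class shares. Some genes that the rule picked or the lists hold are not reported here by name, though the counts include them. Within a class the 4 largest in each direction were taken at a mean of at least 50 CPM, without the condition on the class-adjusted fit. The planned test within classes required at least 20 cells in each of the 6 mice, which no epithelial class met. The rule used instead, at least 20 cells in each of the 4 mice of a pair of strains, was chosen after the cell numbers were seen, as were fits on epithelial cells alone. Strain-only transcripts, used to place cells in a strain, had at least 30 CPM in the epithelial cells of a strain and at most 2% of that in the others. They were chosen on 1 mouse per strain and read in the other, and a cell was placed with at least 3 such UMIs, 80% of them from the same strain. As a further check, added after the placements were seen, each epithelial class was read with genes chosen in both mice on the other epithelial classes.

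On simulated counts for BALB/c against B6, the gene test found 61 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and it called 6 of 15234 unchanged genes. The changed genes averaged at least 20 CPM. Each gene varied exactly at the fitted dispersion trend, with no spread of its own and no differences in class shares. For the real sums the test may therefore find fewer changes and make more false calls. The composition test found 83 of 100 classes changed 4-fold and called 10 of 1100 unchanged ones. Alternatives covered 2 other hashtag callers (MULTIseqDemux and a margin rule with a lead of 1 natural log unit and at least 50 hashtag UMIs), other cell filters, other clustering resolutions, clustering without genes called between strains, TMM or relative log expression scaling, DESeq2 1.42.0, no gene filter, 123 cells from each mouse, the replicate number as a block, and each mouse left out in turn. A strain left with 1 mouse was then assumed to vary like the others. Intervals on counts and shares are 95% exact intervals and cover counting error only. The limit for a count of 0 uses 3 counts. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, leidenalg 0.10.2 and R 4.3.3. Genes with near-identical copies, such as pseudogenes, ribosomal protein genes and the H2-T, Skint, Trim12 and Trim30 families, are uncertain wherever they are named, because the counting could assign their reads to a relative.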

Results

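The comparison asked how mimetic cells of the thymic medulla differ between 3 inbred mouse strains, B6, BALB/c and NOD. A total of 1575 cells was assigned to 6 mice, with 216 and 230 cells in the B6 mice, 360 and 512 in the BALB/c mice and 134 and 123 in the NOD mice (numbers 1 and 2 of each strain). Their summed UMI counts were 3839793 and 4321497 in B6, 6204495 and 8369531 in BALB/c and 3052709 and 2550497 in NOD, so the NOD values rest on the fewest cells and UMIs. Depth per cell was alike, with medians between 13033 UMIs (BALB/c 2) and 16158.5 UMIs (NOD 1) and between 3922.5 and 4535 genes. The median mitochondrial share was 1.496% and 1.524% in the NOD mice and between 2.29% and 2.67% in the other mice.

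H2-Ea, a class II gene with a deleted promoter in the haplotypes of B6 and NOD and an intact one in BALB/c, was read first as a check of the link from hashtag to strain. The gene lies on chromosome 17 at 34341959 to 34344645, minus strand (mm10), and is annotated as a polymorphic pseudogene. Over all assigned cells the check did not separate the strains. H2-Ea reached 299.8 and 1102 CPM in B6, 1074 and 1039 CPM in BALB/c and 1363 and 1554 CPM in NOD. Most of the signal under B6 and NOD hashtags lay in leukocyte-like cells. Myeloid or dendritic cell-like cells held 6401 CPM of H2-Ea under B6 hashtags, 5035 under BALB/c and 6903 under NOD hashtags. Tuft-like cells held 19.3, 33.6 and 9.98. In epithelial cells alone, a reading added after this was seen, H2-Ea stood at 39.4 and 72.4 CPM in B6, 877 and 831 CPM in BALB/c and 42.6 and 93.1 CPM in NOD. Of these epithelial H2-Ea UMIs, 293 of 384 under B6 and 203 of 265 under NOD hashtags lay in proliferating-like cells. Those cells held 539, 3106 and 145 CPM under B6, BALB/c and NOD hashtags. Strain-only transcripts placed 285 of 288 epithelial cells under B6 hashtags as B6 (98.96%), 691 of 694 as BALB/c (99.57%) and 112 of 117 as NOD (95.7%). Of 7 placed enterocyte-hepatocyte-like cells under NOD hashtags, 4 were placed as NOD and 3 as B6. With genes chosen in the other epithelial classes, 5 of 6 were placed as NOD and 1 as B6, but of 31 such cells under BALB/c hashtags 8 were then placed as B6. Placement in this class thus varied with the genes used, which in the second reading included Reg3g, a leading gene of the class. Transcripts that were B6-only in both B6 mice stood at 1040 CPM in this class under B6 hashtags. In its 11 cells under NOD hashtags they had 0 UMIs, beside 140 NOD-only UMIs. These 5 B6-only genes were chosen on sums that included those cells, but all were also picked from the other epithelial classes alone. The wider set picked there, with Reg3g in it, had 536 UMIs in the same 11 cells. The 5 genes thus argue against mislabelled B6 cells there, while the wider set cannot decide, because it holds genes of the class. The hashtags therefore separated strains in epithelial cells as a whole, and shares of leukocyte-like cells under a hashtag are reported without a strain reading. Gene sums over all cells still include leukocyte-like cells, so those strain contrasts also carry RNA of cells whose strain was not established. Myeloid or dendritic cell-like cells alone held 854510 UMIs under B6, 709470 under BALB/c and 1137621 under NOD hashtags.

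**Figure D1:**
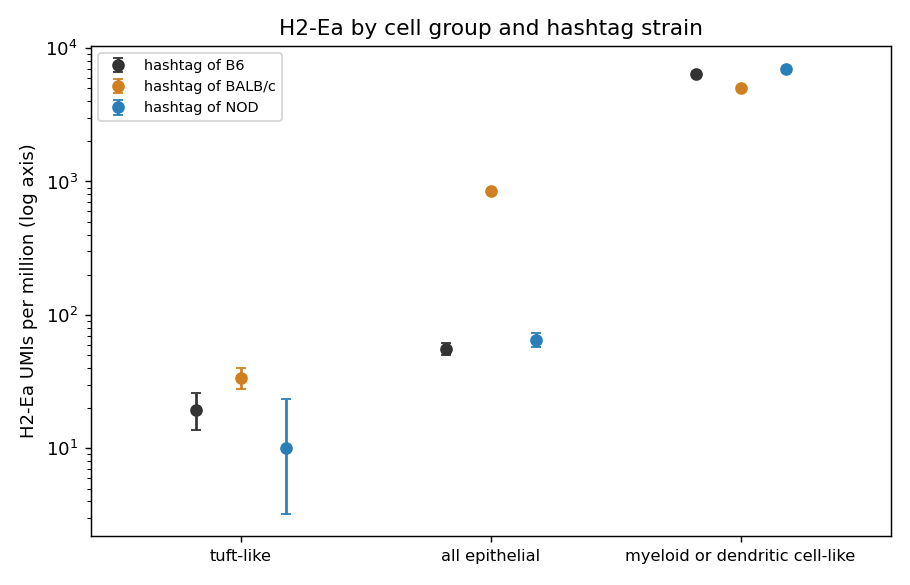
H2-Ea in CPM (log axis) in tuft-like, all epithelial and myeloid or dendritic cell-like cells, coloured by the strain of the hashtag; points are sums over the cells and bars 95% exact Poisson intervals, which cover counting error only. Tuft-like cells lie between 9.98 and 33.6, while myeloid or dendritic cell-like cells lie between 5035 and 6903 under all 3 strains' hashtags.

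The 19 clusters fell into 15 classes. Tuft-like cells, which resemble the chemosensory cells of mucosal surfaces, were the most numerous class in B6 and BALB/c. Microfold-like cells were led by Ccl20, Hamp and Ccl6, neuroendocrine-like cells by Stxbp5l and Chgb, and enterocyte-hepatocyte-like cells by Spink1 and Reg3g. The proliferating-like cluster was also led by Aire. Cluster 2 was led by Tagln, Ccl21a and Acta2, cluster 8 by Col6a2, Kcnip4 and Col6a1, and cluster 10 by Mybpc1. The classes compared come from cells sorted without Pdpn and CD104, so shares refer to that gate. With the genes called between strains in the class-adjusted fit left out before clustering, 33 of 36 class tests came out the same and 3 were stronger. Shares are therefore compared below, though genes particular to classes absent from that fit could not be left out.

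Between BALB/c and B6, microfold-like cells, which resemble the antigen-sampling cells over gut lymphoid tissue, made up 8.50% ± 0.891 of B6 cells (SD, n = 2) and 0.334% ± 0.0798 of BALB/c cells (n = 2), from 38 and 3 cells. The fitted difference was 21.9-fold (log2 -4.45, SE 0.71, edgeR adjusted p = 1.54e-06). Neuroendocrine-like cells stood at 8.88% ± 4.05 in B6 and 1.64% ± 1.22 in BALB/c (log2 -2.51, SE 0.60, adjusted p = 0.000675). Clusters 2, 5 and 10 were larger in BALB/c. Cluster 2 stood at 12.5% ± 3.90 against 1.77% ± 1.19 (log2 2.78, SE 0.68, adjusted p = 0.000675), cluster 5 at 10.3% ± 0.0522 against 1.33% ± 0.575 (log2 2.90, adjusted p = 0.000792) and cluster 10 at 8.66% ± 0.460 against 1.80% ± 0.0797 (log2 2.24, adjusted p = 0.00441). Cluster 8 stood at 5.51% ± 0.0614 against 1.30% ± 1.84 (log2 2.00, adjusted p = 0.0274). That call was lost without B6 1, BALB/c 1, BALB/c 2, NOD 1 or NOD 2, with a highest adjusted p of 0.167 and a log2 difference of 1.06 without B6 1. Summed, clusters 2, 5, 8 and 10 took 3.70% and 8.70% of the B6 mice and 33.9% and 40.04% of the BALB/c mice (log2 2.56, edgeR adjusted p = 2.69e-05), a sum chosen after the clusters were seen. Tuft-like cells (27.1% ± 0.951 against 39.7% ± 11.3, adjusted p = 0.178), ciliated-like (0.133), keratinocyte-like (0.660) and proliferating-like cells (0.133) were not called. Enterocyte-hepatocyte-like cells (log2 -1.11, adjusted p = 0.0757) would be called without B6 2 (0.0305), proliferating-like cells without B6 1 (0.0445) and myeloid or dendritic cell-like cells (0.0837) without B6 1 (0.00696). Cluster 2 missed the threshold when only cells under 10% mitochondrial UMIs were kept (adjusted p = 0.0607, range over alternatives 0.000197 to 0.0607). Exact permutation over the 6 mice tested for a difference among all 3 strains, not for BALB/c against B6. Its p was 0.0667, the smallest possible, for tuft-like, microfold-like, enterocyte-hepatocyte-like and proliferating-like cells and clusters 5 and 8. It was 0.2 for clusters 2 and 10 and 0.133 for neuroendocrine-like cells.

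Between NOD and B6, tuft-like cells stood at 10.6% ± 4.496 in NOD and 39.7% ± 11.3 in B6 (n = 2 each), 3.74-fold lower (log2 -1.90, SE 0.48, edgeR adjusted p = 0.000978). Tuft-like cells under NOD hashtags were tagged more weakly, with a median of 641 hashtag UMIs and 79.7% on the leading hashtag. Under B6 hashtags these were 2819 and 96.7%. Whether more NOD tuft-like cells were lost at hashtag calling was not tested directly. Under the margin rule, which left 103 passing barcodes without a hashtag, the difference was log2 -1.99 (edgeR adjusted p = 1.59e-05). No microfold-like cell was found among 134 cells of NOD 1 or 123 of NOD 2, which allows shares of up to 2.24% and 2.44%, against 8.50% ± 0.891 in B6 (adjusted p = 6.60e-05). Cluster 8 stood at 17.97% ± 2.19 in NOD (log2 3.70, SE 0.75, adjusted p = 6.60e-05) and proliferating-like cells at 16.2% ± 3.42 against 3.40% ± 1.74 (log2 2.26, SE 0.65, adjusted p = 0.0028). Cluster 2 (12.4% ± 2.55, log2 2.76, adjusted p = 0.00175) and cluster 5 (8.24% ± 2.15, log2 2.57, adjusted p = 0.00637) were larger in NOD. The cluster 2 call ended under 10% mitochondrial UMIs (0.0799, range over alternatives 0.000486 to 0.0799) and the cluster 5 call under the margin rule (log2 0.40, adjusted p = 0.720, range 0.00102 to 0.720). Neuroendocrine-like cells stood at 1.59% ± 1.20 (log2 -2.48, adjusted p = 0.00613), a call lost without NOD 1 or NOD 2 (highest adjusted p = 0.185, without NOD 1). Enterocyte-hepatocyte-like cells stood at 4.27% ± 0.292 against 13.03% ± 1.21 (log2 -1.60, adjusted p = 0.035), lost without BALB/c 1, NOD 1 or NOD 2 (highest 0.103, without NOD 1). The summed clusters 2, 5, 8 and 10 took 42.5% and 40.7% of the NOD mice (log2 2.73, edgeR adjusted p = 3.73e-05). Ciliated-like cells (0.856), keratinocyte-like cells (0.474) and cluster 10 (0.474) were not called, nor were myeloid or dendritic cell-like cells (11.6% ± 1.497 against 4.62% ± 3.92, adjusted p = 0.0521), which would be called without B6 2 (0.00265).

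Between NOD and BALB/c, cluster 8 was larger in NOD (log2 1.69, SE 0.56, edgeR adjusted p = 0.0234) and tuft-like cells fewer, 2.56-fold (log2 -1.36, SE 0.48, adjusted p = 0.0266). Tuft-like cells under BALB/c hashtags were also better tagged than those under NOD hashtags (median 2412 hashtag UMIs, 96.9% on the leading hashtag). Myeloid or dendritic cell-like cells stood at 11.6% ± 1.497 under NOD hashtags and 1.85% ± 0.132 under BALB/c hashtags (adjusted p = 0.00193), without a strain reading. The cluster 8 and tuft-like calls were each lost without BALB/c 1, BALB/c 2, NOD 1 or NOD 2, with highest adjusted p of 0.286 (without NOD 2) and 0.320 (without NOD 1), and the myeloid call without NOD 1 (0.144) or NOD 2. With MULTIseqDemux the myeloid difference turned to log2 -1.21 (adjusted p = 0.670, range over alternatives 0.000164 to 0.670). Without either NOD mouse 0 of the 12 classes were called by edgeR, with 2 and 3 at an unadjusted p under 0.05. TMM scaling of the cell numbers also ended the tuft-like call (0.138), as did a bound of 10% mitochondrial UMIs (0.072), with a range over alternatives of 0.000934 to 0.320. Proliferating-like cells (log2 1.22, adjusted p = 0.0937) and cluster 10 (log2 -1.47, adjusted p = 0.0978) were not called but would be without B6 1 or B6 2, with lowest adjusted p of 0.0191 and 0.0358. The summed clusters 2, 5, 8 and 10 differed by log2 0.17 (edgeR adjusted p = 0.773). Muscle-like cells, too few to test, numbered 1, 27 and 0 in B6, BALB/c and NOD. Strain-only transcripts placed the 1 cell under a B6 hashtag as BALB/c, but genes chosen on the other classes left it unplaced. B or plasma cell-like cells numbered 8, 13 and 7, and thymocyte-like cells 9, 6 and 5.

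**Figure D2:**
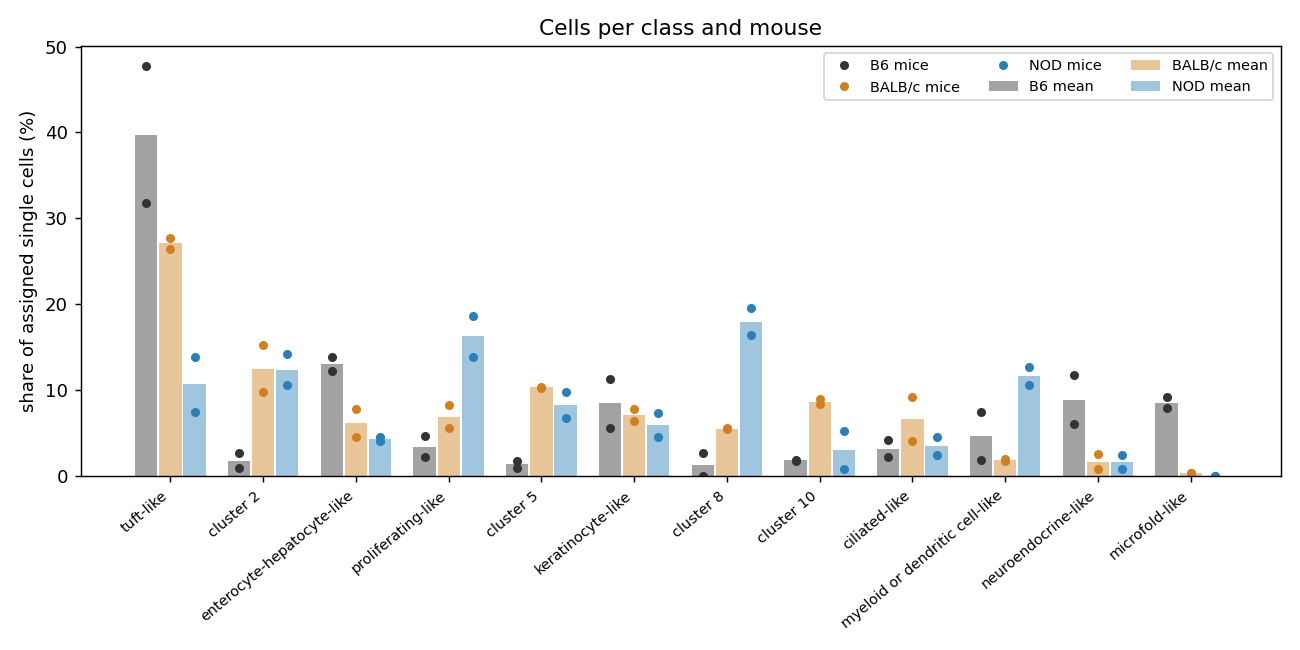
Share of assigned single cells (percent, linear axis from 0) in each of the 12 tested classes, with a point for each mouse and a bar for the mean of the 2 mice of a strain. Tuft-like cells make up 47.7% and 31.7% of the B6 mice, 26.4% and 27.7% of the BALB/c mice and 7.46% and 13.8% of the NOD mice, and microfold-like cells stand at 8.50% on average in B6, 0.334% in BALB/c and 0% in NOD.

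Summed over all cells, BALB/c mice had higher levels of interferon-stimulated genes than B6 mice and lower levels of microfold and enterocyte-hepatocyte genes. Sparc and Acta2 were among the single genes that were higher in BALB/c. Of 33 interferon-stimulated genes, 23 rose and 0 fell, with 28 risen when adjusted over the list alone (edgeR; at an unadjusted p under 0.05, 4106 of all 15888 genes). Camera gave an adjusted p of 1.72e-17 for the list, and the adjusted p = 0.315 with an estimated correlation. Isg15, a ubiquitin-like interferon effector, stood at 373 ± 32.4 CPM (SD, n = 2) against 132 ± 48.6 (log2 1.503, adjusted p = 0.0219). Iigp1, an interferon-inducible GTPase, rose by log2 2.71 (0.00177). The list also rose in the class-adjusted fit (camera adjusted p = 1.34e-09), where 13 members rose, and 27 members rose in epithelial cells alone.

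Sparc, a collagen-binding matrix protein, was 66.0 ± 11.97 CPM in BALB/c and 1.96 ± 0.175 CPM in B6 (log2 5.06, SE 0.31, adjusted p = 0.000792). The gene lies on chromosome 11 at 55394500 to 55423183, minus strand, and leads a tuft-like cluster. Its difference fell to log2 1.76 with MULTIseqDemux (adjusted p = 0.339) and to 1.98 under the margin rule (0.226), with adjusted p from 1.87e-76 to 0.339 over its alternatives. The matrix genes Antxr1 (log2 3.47, a collagen receptor), Col12a1 (2.94) and Col6a1 (2.85), the smooth muscle actin gene Acta2 (3.06) and the tetraspanin gene Cd81 (2.52) were higher in BALB/c. So were the chemokine gene Cxcl11 (3.49), the interferon-induced Ifi44 (2.80) and the muscle gene Mybpc1 (2.59). Acta2 and Cxcl11 are among the leading genes of cluster 2, Col6a1 of cluster 8 and Mybpc1 of cluster 10, clusters that were larger in BALB/c. These genes also passed the class-adjusted fit, as the naming rule required. That fit held no B6 sum for clusters 2 and 8 and left out cluster 10. Ndufa12-ps rose by log2 3.25. Tmem181c-ps, an unprocessed pseudogene on chromosome 17 (6613753 to 6639790, minus strand), had 3367 counts in BALB/c and 2 in B6, a ratio of 910 (interval 252 to 7521). Lower in BALB/c were Spock3 (log2 -3.93, adjusted p = 0.000202), the guanine deaminase gene Gda (-3.65), Cntnap2 (-3.20), the retroviral restriction gene Apobec3 (-2.01), Septin1 (-2.07) and Rpl26 (-2.57). The gut galectin gene Lgals4 was also lower (log2 -3.45). Fcgbp, a mucus protein gene on chromosome 7 (28071236 to 28120862, plus strand), stood at 65.9 ± 11.3 CPM against 619 ± 132 (log2 -3.23, adjusted p = 0.00197). Serpinb1a, an inhibitor of neutrophil proteases, stood at 194 ± 24.8 CPM against 1566 ± 34.8 (log2 -3.01, adjusted p = 0.00272). In a class-adjusted fit on epithelial cells alone Serpinb1a fell by only log2 -0.82 and Lgals4 by -1.68. Fcgbp (-3.54) and Cntnap2 (-3.94) kept their size there. Gsto1 (-2.42), a leading gene of the enterocyte-hepatocyte-like cluster, AW112010 (-2.999) and Ccl25 (-2.59), a chemokine that draws thymocyte precursors, were also lower. The Ccl25 call ended with MULTIseqDemux (-1.45, 0.114) and the margin rule (-0.79, 0.548), with a range of 4.43e-38 to 0.548 over its alternatives.

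Microfold markers fell in BALB/c, with 8 of 10 lower and 10 lower adjusted over the list alone (camera adjusted p = 1.03e-12, adjusted p = 0.315 with an estimated correlation). Ccl20, a chemokine for CCR6-bearing cells, stood at 29.7 ± 3.30 CPM against 1309 ± 22.8, and the lineage factor gene Sox8 fell by log2 2.28. Of 13 enterocyte-hepatocyte markers 7 fell, 10 adjusted over the list alone (1.59e-09, adjusted p = 0.315 with an estimated correlation), among them the fatty acid carrier gene Fabp1 (log2 -4.56) and Vil1 of the brush border (-2.25). Of 25 mimetic lineage transcription factors 7 fell and Trp63 rose, the same adjusted over the list alone (0.0199, adjusted p = 0.315 with an estimated correlation, 0.067 without BALB/c 1). Foxa1 (-1.96), Ptf1a (-3.51) and Spib (-1.08) were among those lower. Of 10 islet autoantigens Ica1 and Scg2 fell, 4 adjusted over the list alone (0.000174, adjusted p = 0.348 with an estimated correlation). Scg2 was also the neuroendocrine marker that fell of 13, 1 adjusted over the list alone (0.00111, adjusted p = 0.457 with an estimated correlation). The pancreatic markers Prss2 and Ptf1a fell of 6, 4 adjusted over the list alone (0.00867, adjusted p = 0.315 with an estimated correlation). Fcgbp fell of 12 secretory markers, 1 adjusted over the list alone (0.0199, adjusted p = 0.457 with an estimated correlation, 0.103 without BALB/c 1). Pglyrp1 and Pigr fell and Slpi rose of 14 antimicrobial genes, the same adjusted over the list alone (0.0232, adjusted p = 0.746 with an estimated correlation, 0.150 without BALB/c 1).

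Of 7 immature mTEC markers 5 rose in BALB/c, 5 adjusted over the list alone (0.000152, adjusted p = 0.315 with an estimated correlation). The list was not called in the class-adjusted fit (median log2 0.65, camera adjusted p = 0.0947, 1 of 6 higher). The CCR7 ligand gene Ccl21a stood at 1994 ± 531 CPM against 380.2 ± 207, and Pdpn (log2 2.50) and Itgb4 (1.21), whose proteins the sort gated against, rose as well. Of 6 pericyte or smooth muscle markers Acta2 and Myh11 rose, 3 adjusted over the list alone (0.016, adjusted p = 0.315 with an estimated correlation). Of 10 muscle markers Acta1, Ckm, Des and Tnnt3 rose, 6 adjusted over the list alone (0.000425, adjusted p = 0.315 with an estimated correlation), beside 27 muscle-like cells in BALB/c and 1 in B6. Of 9 epithelial keratins Krt5, Krt14 and Krt7 rose and Krt20 fell, the same adjusted over the list alone. The list was called up (0.0482, adjusted p = 0.348 with an estimated correlation) with a median of log2 0.33 and a mean of -0.14. That call was lost without B6 1 (0.0676), BALB/c 2 (0.0718), NOD 1 (0.0587) or NOD 2 (0.0552) and in epithelial cells alone (0.137). Of 136 genes with ribosomal protein symbols, 42 of them pseudogenes and 10 kinase or binding protein genes, 3 rose and 5 fell, the same adjusted over the list alone. The 3 that rose were pseudogenes, and of the 84 ribosomal protein genes 0 rose and 4 fell. The list was called up (0.000425, adjusted p = 0.746 with an estimated correlation). Of the leukocyte lists, thymocyte markers (1 of 10 lower, Cd8b1, 7 adjusted over the list alone, 0.00276, adjusted p = 0.457 with an estimated correlation) and myeloid markers (1 of 9 lower, Itgam, 1 adjusted over the list alone, 0.0199, adjusted p = 0.605 with an estimated correlation) were called down. Both missed the threshold in epithelial cells alone (0.428 and 0.0626). The myeloid call was lost without B6 2 (0.376) or BALB/c 2 (0.0989).

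For BALB/c against B6 edgeR called 738 genes higher and 836 lower, and DESeq2 699 and 933. In the class-adjusted fit 275 were higher and 213 lower of 8124, and 279 of 987 genes called over all cells and tested there were called in both with the same sign. The counts fell without B6 1 (309 higher, 415 lower), B6 2 (415, 421), BALB/c 1 (253, 257) and BALB/c 2 (158, 170). Named calls lost without 1 mouse were AW112010 and Acta2 (B6 1, B6 2, BALB/c 1 or BALB/c 2, highest adjusted p = 0.262 and 0.144), Col6a1 (BALB/c 1, BALB/c 2, NOD 1 or NOD 2, 0.203), Cxcl11 and Mybpc1 (B6 1, BALB/c 1 or BALB/c 2, 0.196 and 0.188), Cd81 and Cntnap2 (BALB/c 1 or BALB/c 2, 0.0682 and 0.0603), and Ccl25 and Gsto1 (BALB/c 2, 0.0633 and 0.0622). Each of these highest values was without BALB/c 2. With equal cells per mouse the calls of Ifi44 (0.107, range over alternatives 1.41e-43 to 0.107), Cxcl11 (0.165), Mybpc1 (0.130) and Acta2 (0.0913) ended, and in epithelial cells alone those of Col6a1 (0.0517), Mybpc1 (0.0532) and AW112010 (0.0692).

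Summed over all cells, NOD mice had lower levels of tuft, microfold and enterocyte-hepatocyte genes than B6 mice and higher levels of interferon-stimulated, cell cycle, ribosomal protein and MHC class II genes. Dclk1, a kinase gene that marks tuft cells, stood at 102 ± 0.884 CPM in NOD and 971 ± 59.0 CPM in B6 (SD, n = 2 each, log2 -3.25, SE 0.16, edgeR adjusted p = 0.00038). It lies on chromosome 3 at 55242364 to 55539068, plus strand, and leads a tuft-like cluster. The Dclk1 difference was log2 -1.46 in a class-adjusted fit on epithelial cells alone. Of 15 tuft markers 6 fell, 9 adjusted over the list alone (camera adjusted p = 6.95e-06, adjusted p = 0.494 with an estimated correlation), among them the lineage factor gene Pou2f3 (log2 -1.98, 0.0138) and Avil (-1.45, 0.00826). Of 14 tuft effectors 6 fell, 8 adjusted over the list alone (8.5e-05, adjusted p = 0.494 with an estimated correlation), among them the acetylcholine synthesis gene Chat (-2.05), the IL-25 receptor gene Il17rb (-2.07) and the ion channel gene Trpm5 (-1.67). These falls stand beside the lower share of tuft-like cells. In the class-adjusted fit neither list was called, with the tuft markers turned upward (median log2 0.21, camera adjusted p = 0.952) and the effectors still down (adjusted p = 0.894).

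Interferon-stimulated genes rose in 29 of 33 in NOD against B6 and fell in 0, with 30 adjusted over the list alone (6.66e-16, adjusted p = 0.345 with an estimated correlation). Isg15 stood at 449 ± 49.3 CPM, and Cxcl10, a T cell chemokine, at 396 ± 93.6 against 111 ± 49.6 (log2 1.83, 0.0255). Iigp1, on chromosome 18 at 60376027 to 60392634, plus strand, stood at 209 ± 60.3 CPM against 24.8 ± 1.58 (log2 3.07, 0.00114). Its difference was log2 1.41 in a class-adjusted fit on epithelial cells alone. The list rose in the class-adjusted fit as well (camera adjusted p = 5.13e-12, 11 members higher), and 30 members rose in epithelial cells alone. Of 10 proliferation markers 7 rose, 7 adjusted over the list alone (1.04e-05, adjusted p = 0.345 with an estimated correlation), among them the mitotic genes Birc5 (log2 1.35), Cdk1 (1.72) and Ube2c (2.38). Proliferating-like cells made up 16.2% of NOD and 3.40% of B6 cells, and in the class-adjusted fit the list was not called (median log2 -0.14, camera adjusted p = 0.952). Of the 136 genes with ribosomal protein symbols 93 rose and 3 fell, 98 and 3 adjusted over the list alone (8.58e-30, adjusted p = 0.345 with an estimated correlation). The median of the list fell in the class-adjusted fit from log2 0.78 to 0.18, with 6 higher and 3 lower of 105 (camera adjusted p = 0.000129). Of the 84 ribosomal protein genes among them 77 rose and 1 fell over all cells, and 0 rose and 3 fell in that fit. Of 19 mitochondrially encoded genes 7 fell, 8 adjusted over the list alone (1.65e-05, adjusted p = 0.469 with an estimated correlation), beside the lower mitochondrial share of NOD cells. The rRNA gene mt-Rnr2 stood at 6277 ± 149.6 CPM against 9823 ± 833.

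Of 12 MHC class II presentation genes 7 rose in NOD against B6, 8 adjusted over the list alone (1.65e-05, adjusted p = 0.345 with an estimated correlation). The invariant chain gene Cd74 stood at 9333 ± 1507 CPM against 5217 ± 1065, H2-Aa rose by log2 0.89 and the class II regulator gene Ciita by 1.21. Myeloid or dendritic cell-like cells made up 11.6% of cells under NOD hashtags and 4.62% under B6 hashtags. In epithelial cells alone 7 rose and 1 fell, and the class-adjusted fit gave the list the opposite direction. Of 7 Aire-stage mTEC markers Cd40 and Ciita rose, 2 adjusted over the list alone (0.0172, adjusted p = 0.506 with an estimated correlation, 0.0964 without NOD 1), and this list also turned downward in the class-adjusted fit (0.580). Of 7 immature mTEC markers 5 rose and Ackr4 fell, the same adjusted over the list alone (0.00143, adjusted p = 0.345 with an estimated correlation), with Pdpn up by log2 2.86. It was not called in the class-adjusted fit (median log2 0.63, camera adjusted p = 0.114, 2 of 6 higher). Acta2 (3.27) and Myh11 (1.23) rose of 6 pericyte or smooth muscle markers, 4 adjusted over the list alone (0.00929, adjusted p = 0.345 with an estimated correlation). Microfold markers fell in 8 of 10, 8 adjusted over the list alone (1.07e-09, adjusted p = 0.345 with an estimated correlation), with Ccl20 at 7.73 ± 1.64 CPM against 1309 ± 22.8. Enterocyte-hepatocyte markers fell in 9 of 13, 11 adjusted over the list alone (5.67e-07, adjusted p = 0.345 with an estimated correlation), with Vil1 lower by log2 -2.12. Lineage transcription factors fell in 11 of 25, with 13 lower and 1 higher adjusted over the list alone (0.000208, adjusted p = 0.345 with an estimated correlation), among them Elf3 (-1.01), Ehf (-1.04) and Klf5 (-0.76). Ica1 and Scg2 fell of 10 islet autoantigens, 2 adjusted over the list alone (0.00143, adjusted p = 0.444 with an estimated correlation). Scg2 and Scg5 fell of 13 neuroendocrine markers, 2 adjusted over the list alone (0.00485, adjusted p = 0.506 with an estimated correlation). Clps, Prss2, Ptf1a and Rbpjl fell of 6 pancreatic markers, 4 adjusted over the list alone (0.0163, adjusted p = 0.345 with an estimated correlation, 0.130 without NOD 1 and 0.0951 without NOD 2). Bpifa1, Pglyrp1 and Pigr fell and Slpi rose of 14 antimicrobial genes, the same adjusted over the list alone (0.0172, adjusted p = 0.668 with an estimated correlation).

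The largest named changes in NOD against B6 included Rps24-ps3, a processed pseudogene on chromosome X (79195047 to 79195448, plus strand) with 353 ± 35.1 CPM against 1.75 ± 1.74 (log2 7.58, adjusted p = 0.00145). Sparc (log2 4.88, adjusted p = 0.00101), the collagen VI genes Col6a1 (4.46) and Col6a2 (4.11), both leading genes of cluster 8, and Antxr1 (3.46) were higher in NOD. The Sparc difference fell to 2.01 with MULTIseqDemux (0.207) and 2.15 under the margin rule (0.138), with a range of 1.45e-66 to 0.207 over its alternatives. The long noncoding RNA gene Rmst (3.04) and the gene copies Ndufa12-ps (3.69), Csnk2a3 (3.04) and Tpm3-rs7 (2.90) were higher as well. Lower in NOD were the milk casein gene Csn2 (log2 -4.51, a leading gene of the microfold-like cluster), the synaptic genes Rims2 (-3.19) and Tenm2 (-2.83), the intestinal regulator gene Hnf4g (-3.39), the leukotriene receptor gene Cysltr2 (-2.82) and the calcium channel gene Cacna1c (-2.50). Myo15b (-2.79), Mctp2 (-2.49), Bnip5 (-2.33) and the nonclassical class I gene H2-T22 (-2.70) were lower as well. Hnf4g (0.0823) and Myo15b (0.0558) missed the threshold in a class-adjusted fit on epithelial cells alone. Calls lost without 1 mouse were Csn2 (B6 1, B6 2, BALB/c 1, BALB/c 2 or NOD 2, highest adjusted p = 0.104, without B6 1), Cacna1c (B6 1, B6 2, BALB/c 1 or BALB/c 2, 0.113, without B6 1), Col6a2 (NOD 1 or NOD 2, 0.0781, without NOD 1), Col6a1 (NOD 1, 0.0528) and Acta2 (B6 1, 0.0534). With equal cells per mouse the calls of Col6a2 (0.0539) and Csn2 (0.0601) ended. In all, 1531 genes were higher and 1588 lower by edgeR, 1335 and 1444 by DESeq2, and 287 and 308 of 8124 in the class-adjusted fit. Without B6 1 the counts were 538 and 660, without NOD 1 537 and 722, without NOD 2 872 and 1025, without BALB/c 1 1003 higher and without BALB/c 2 981 higher.

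Between NOD and BALB/c, NOD had higher ribosomal protein, cell cycle and MHC class II levels and lower tuft levels summed over all cells. Of the 136 genes with ribosomal protein symbols 82 rose and 0 fell, 103 and 1 adjusted over the list alone (camera adjusted p = 1.11e-31, adjusted p = 0.536 with an estimated correlation). With class in the model the median of the list fell from log2 0.62 to 0.06, with 5 higher and 3 lower of 105 (camera adjusted p = 0.0194). Of the 84 ribosomal protein genes among them 75 rose and 0 fell over all cells, and 2 rose and 3 fell in that fit. Of 10 proliferation markers 7 rose, 9 adjusted over the list alone (1.07e-07, adjusted p = 0.536 with an estimated correlation), with Ube2c at 126 ± 52.7 CPM against 26.9 ± 0.965 (SD, n = 2 each, log2 2.22, edgeR adjusted p = 0.0196). In the class-adjusted fit the proliferation list was not called (camera adjusted p = 0.591), beside 16.2% proliferating-like cells in NOD and 6.88% in BALB/c. Of 15 tuft markers 6 fell, with 10 lower and 1 higher adjusted over the list alone (1.75e-07, adjusted p = 0.566 with an estimated correlation), among them Dclk1 (log2 -2.43, 0.00265), Pou2f3 (-1.51) and Gnat3 (-1.29), the taste G protein gene. Of 14 tuft effectors 7 fell, with 9 lower and 1 higher adjusted over the list alone (2.88e-05, adjusted p = 0.566 with an estimated correlation), among them Chat (-1.74) and Il17rb (-1.60). Both tuft lists turned upward in the class-adjusted fit and were not called there (camera adjusted p = 0.481 and 0.291). The Dclk1 difference was -1.86 with MULTIseqDemux (0.0792) and -1.69 under the margin rule (0.143), with a range of 1.48e-60 to 0.143 over its alternatives. With class in the model, in epithelial cells alone, it was log2 -1.23. Of 12 class II genes 9 rose, 11 adjusted over the list alone (2.97e-08, adjusted p = 0.536 with an estimated correlation), with Cd74 up by log2 1.14 and H2-Ab1 by 1.24. In epithelial cells alone 2 of the 12 rose. Leukocyte markers moved with them. Thymocyte markers rose in 4 of 10, 7 adjusted over the list alone (2.86e-05, adjusted p = 0.536 with an estimated correlation), and in epithelial cells alone the list was not called (0.848). Xcr1 rose of 9 myeloid markers, 1 adjusted over the list alone (0.00708, adjusted p = 0.599 with an estimated correlation), and in epithelial cells alone the list was not called (0.746). Cd86, a T cell costimulator gene, rose of 8 costimulation genes, 3 adjusted over the list alone (0.00573, adjusted p = 0.566 with an estimated correlation, 0.111 without NOD 1). Cd86 was also the Aire-stage marker that rose of 7, 4 adjusted over the list alone (0.00573, adjusted p = 0.566 with an estimated correlation, 0.194 without NOD 1). The gene is among the leading genes of a myeloid or dendritic cell-like cluster. Cells of that class made up 11.6% under NOD and 1.85% under BALB/c hashtags.

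Psmb8 and Psmb9, subunit genes of the immunoproteasome, rose in NOD against BALB/c and H2-D1 and H2-T22 fell, of 16 MHC class I genes, with 5 higher and 2 lower adjusted over the list alone. That list was called up (0.0253, adjusted p = 0.807 with an estimated correlation) and lost without BALB/c 1 (0.0606), without NOD 1 (0.283) and in epithelial cells alone (0.0581). Lineage transcription factors fell in 5 of 25, with 7 lower and 1 higher adjusted over the list alone (0.00708, adjusted p = 0.536 with an estimated correlation, 0.0669 in epithelial cells alone), among them Elf3 (log2 -1.20) and Spib (-0.60). Sprr2d rose of 13 cornified envelope genes, 2 adjusted over the list alone (0.00785, adjusted p = 0.614 with an estimated correlation, 0.1002 without BALB/c 1). Of 19 mitochondrially encoded genes mt-Atp8, mt-Rnr1 and mt-Rnr2 fell, 10 adjusted over the list alone (2.4e-05, adjusted p = 0.566 with an estimated correlation). The muscle genes Acta1 and Ckm fell of 10, 5 adjusted over the list alone (0.0239, adjusted p = 0.536 with an estimated correlation, 0.0725 without NOD 2). Interferon-stimulated genes were not called (0.592). The largest named changes were Rps24-ps3 (log2 6.72), Csnk2a3 (3.95) and Fcgbp, at 958 ± 208 CPM against 65.9 ± 11.3 (3.86, adjusted p = 0.0036). Kcnip4 (3.76, a leading gene of cluster 8), Ang2 (3.12), the cartilage matrix gene Matn1 (2.95), H2-T10 (2.70), Gda (2.29), Sntg1 (2.20), the CCR7 ligand gene Ccl19 (2.14) and the ceramide synthesis gene Degs1 (1.96) were higher in NOD. Rpl26, on chromosome 11 at 68901583 to 68906989, plus strand, stood at 1654 ± 33.0 CPM against 177 ± 29.4 (3.22). Tmem181c-ps had 9 counts in NOD and 3367 in BALB/c. Rims2 (log2 -2.88), H2-T22 (-2.85), the ubiquitin gene Ubb (-2.36), Aox4 (-2.15), Mctp2 (-2.07), Trim12c (-1.997), Smim10l1 (-1.87), Ranbp17 (-1.85) and Macrod2 (-1.78) were lower.

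For NOD against BALB/c edgeR called 966 genes higher and 834 lower, DESeq2 1099 and 777, and the class-adjusted fit 286 and 331 of 8124. Without BALB/c 1 the counts were 74 and 79, without BALB/c 2 60 higher and 86 lower, without NOD 1 56 and 43, and without NOD 2 234 and 320. Named calls lost without 1 mouse were Ranbp17 (B6 1, B6 2, BALB/c 1, BALB/c 2 or NOD 2, highest adjusted p = 0.188, without BALB/c 2), Kcnip4 (B6 1, B6 2, BALB/c 2, NOD 1 or NOD 2, 0.105, without NOD 1), Ang2 and Degs1 (BALB/c 1, BALB/c 2 or NOD 1, 0.119 and 0.143, without BALB/c 2), Sntg1 (BALB/c 1, NOD 1 or NOD 2, 0.114, without NOD 1), Smim10l1 (BALB/c 2, NOD 1 or NOD 2, 0.0896, without NOD 1), Mctp2 (BALB/c 1 or BALB/c 2, 0.0716, without BALB/c 1) and Macrod2 (NOD 1, 0.0532). With equal cells per mouse the calls of Ang2 (0.0974), Kcnip4 (0.0610), Ranbp17 (0.0713) and Sntg1 (0.0648) ended.

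Lists not called between BALB/c and B6 (camera adjusted p in parentheses) were MHC class II (0.125), MHC class I (0.804), immediate-early and heat shock genes (0.137), tuft effectors (0.777), chemokines and thymopoietic cytokines (0.103), other organ autoantigens (0.829), cornified envelope (0.12), costimulation (0.124) and mitochondrially encoded genes (0.712). The uncalled marker lists were tuft (0.987), ciliated (0.829), ionocyte (0.229), keratinocyte (0.152), basal (0.0713), Aire-stage mTEC (0.972), proliferating (0.777), cTEC (0.955), B or plasma cell (0.972), endothelial (0.777) and thyroid (0.919). Between NOD and B6 they were MHC class I (0.349), immediate-early (0.952), chemokines (0.998), other organ autoantigens (0.539), cornified envelope (0.18), costimulation (0.252) and keratins (0.349), and the ciliated (0.426), ionocyte (0.679), muscle (0.539), secretory (0.0516), keratinocyte (0.539), basal (0.0516), cTEC (0.399), thymocyte (0.112), B or plasma cell (0.62), myeloid (0.768), endothelial (0.768) and thyroid (0.878) markers. Between NOD and BALB/c, besides interferon, they were immediate-early (0.182), chemokines (0.143), islet autoantigens (0.621), other organ autoantigens (0.475), antimicrobial genes (0.415) and keratins (0.592), and the microfold (0.823), enterocyte-hepatocyte (0.091), ciliated (0.740), ionocyte (0.592), neuroendocrine (0.592), secretory (0.792), pancreatic (0.369), keratinocyte (0.0562), basal (0.592), immature mTEC (0.592), cTEC (0.346), B or plasma cell (0.592), endothelial (0.592), pericyte (0.625) and thyroid (0.785) markers. Median, mean and test differed in sign for uncalled tuft, ciliated, Aire-stage, cTEC and B or plasma cell markers between BALB/c and B6, for immediate-early genes, chemokines, keratins and ionocyte, muscle and myeloid markers between NOD and B6, and for microfold, ionocyte and secretory markers between NOD and BALB/c. Lists called over all cells but not in the class-adjusted fit (camera adjusted p there), besides those given above, were lineage factors (0.145), keratins (0.928), ribosomal proteins (0.0961) and pericyte markers (0.1004) between BALB/c and B6. Between NOD and B6 they were MHC class II (0.1097), lineage factors (0.207), antimicrobial genes (0.207) and microfold markers (0.256). Between NOD and BALB/c they were MHC class II (0.244), MHC class I (0.272), lineage factors (0.787), cornified envelope (0.293), costimulation (0.241), mitochondrially encoded genes (0.0886) and Aire-stage markers (0.880). Lists called in that fit alone were MHC class II (down, 0.00169, 4 of 12 lower) and immediate-early and heat shock genes (up, 0.00127) between BALB/c and B6, other organ autoantigens (down, 0.00837) between NOD and B6 and secretory markers (up, 0.0222) between NOD and BALB/c. Too few genes were left there to test islet autoantigens and enterocyte-hepatocyte, neuroendocrine, pancreatic, muscle, thymocyte and myeloid markers. With an estimated correlation, camera called 0 lists in each contrast, with 4, 3 and 1 at an unadjusted p under 0.05. By fry, which tests whether a list's genes move on balance one way, 10, 11 and 0 lists were called, with 13, 15 and 10 at an unadjusted p under 0.05.

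Within tuft-like cells, BALB/c and B6 could be compared with 95 and 142 cells against 103 and 73. Sparc stood at 232 ± 60.2 CPM against 3.28 ± 1.55 (log2 6.05, edgeR adjusted p = 4.22e-07) and the beta-globin gene Hbb-bs at 337 ± 134 against 1.86 ± 1.09 (7.37, 0.00102). Both lead tuft-like cluster 9, which held 40% and 35.9% of tuft-like cells in the BALB/c mice, while clusters 1 and 7 held 56.3% and 33.0% in B6 1 and 53.4% and 30.1% in B6 2. Pld5 rose by log2 4.34 (4.07e-07), and Tmem181c-ps had 1428 counts against 1. Lower in BALB/c were genes of the Skint family, which are expressed by thymic and skin epithelium. Skint9 (chromosome 4, 112385969 to 112433985, minus strand) had 0 counts against 303, and Skint1 fell by log2 6.20 (4.59e-08). Trim12a had 2 counts against 441. Gp2, a microfold marker, stood at 15.3 ± 8.14 CPM against 419 ± 218 (log2 -4.68, 0.0406), where microfold-like cells made up 8.50% of all B6 cells. That call was lost without BALB/c 1 (0.294) or BALB/c 2 (0.301). In all 1129 genes were higher and 1050 lower of 10868. That total of 2179 was 779 without B6 1, 1146 without B6 2, 1609 without BALB/c 1 and 1162 without BALB/c 2, and 802 by DESeq2.

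Within enterocyte-hepatocyte-like cells (28 and 23 against 30 and 28 cells), H2-Ea had 1170 counts in BALB/c and 6 in B6 (log2 7.96, edgeR adjusted p = 0.0046), and Tmem181c-ps 155 against 0. The calcium release channel gene Itpr1 (4.69, 0.0433) and the apolipoprotein gene Apoc1 (3.41, 0.0433, 0.0831 without B6 1) were higher. Skint3 had 0 counts in BALB/c against 525 in B6, Skint9 0 against 286, Skint4 0 against 279 and the mucosal peptide gene Tff2 0 against 274, from totals of 767857 and 1090121 UMIs. In all 16 genes were higher and 32 lower of 7349, 48 together. The total was 120 without B6 1, 147 without B6 2, 162 without BALB/c 1, 254 without BALB/c 2 and 115 by DESeq2. Within cluster 8, NOD (22 and 24 cells) was compared with BALB/c (20 and 28). Trim30d had 48 counts against 0, Rps24-ps3 47 against 0, Abca13 35 against 0 and the junctophilin gene Jph2 34 against 0. Tmem181c-ps had 0 against 114, the interferon-induced Ifi44l 0 against 52, H2-Ea 2 against 119 and Rims2 1 against 42. The calls of Abca13 (0.214) and Jph2 (0.131) were lost without NOD 1 and that of Rims2 without BALB/c 1 (0.0767). In all 71 genes were higher and 34 lower of 4204, and their total of 105 was 172 without NOD 2 and 37 by DESeq2.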

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

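Of the tests below, those of shared pseudogene reads and of microfold-like cells among barcodes without a single hashtag were set out before their results were seen. The other tests, and the fit comparing tuft-like with enterocyte-hepatocyte-like cells, were chosen after.

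The effect of strain differed between tuft-like and enterocyte-hepatocyte-like cells for 9 of 10786 genes by limma (6 higher and 3 lower, with 1512 at an unadjusted p under 0.05), in a test of the difference between the classes in BALB/c minus B6. Ftl1, a ferritin light chain gene, was higher in BALB/c tuft-like cells (log2 1.44) and lower in BALB/c enterocyte-hepatocyte-like cells (-0.59), a difference of -1.96 (adjusted p = 0.0230). The synaptic scaffold gene Dlg2 was lower in BALB/c tuft-like cells (-3.76, difference 3.59), and Skint1 likewise (-6.16 against -0.91, difference 5.19, adjusted p = 0.0262). Crip1 differed by -2.76 and Hspb11 by -2.36, each higher in BALB/c tuft-like cells and lower in the other class. Eppk1, a cytoskeletal linker gene, differed by 2.98 and Gm23935 by 2.32, each lower in BALB/c tuft-like cells and higher in the other class. The transcription factor gene Sox4 differed by 1.79 (adjusted p = 0.0383), with a rise of log2 1.94 in enterocyte-hepatocyte-like cells, and the rRNA gene mt-Rnr1 by 1.07. The 9 genes were not weighed further, and no biological explanation was tested for them.

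Signal also appeared in barcodes and hashtags that the comparisons did not use. No hashtag was called for 525 passing barcodes. In 376 of them, those other than Ptprc-bearing and keratin-poor barcodes, H2-Ea stood at 4349.6 CPM, with a median of 28435.5 UMIs and 95.5 hashtag UMIs. Hashtags outside this pool held UMIs as well, 3282 for HT4, 3249 for HT9 and 3303 for HT12.

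H2-Ea was high in myeloid or dendritic cell-like cells under B6 and NOD hashtags, strains in which its promoter is deleted. B or plasma cell-like cells held 122, 904 and 18.8 CPM under B6, BALB/c and NOD hashtags, and thymocyte-like cells 202, 332 and 0. Free RNA from BALB/c cells is argued against, since it would reach every class, while H2-Ea stood at 6903 CPM in myeloid or dendritic cell-like cells under NOD hashtags and at 9.98 in tuft-like cells under the same hashtags. Of the placed myeloid or dendritic cell-like cells, 4 of 8 under B6 and 2 of 4 under NOD hashtags were placed as BALB/c. BALB/c cells given another hashtag remain open. In cells with at least 90% of hashtag UMIs on the leading hashtag, BALB/c-only transcripts stood at 11.2 CPM under NOD, 8.58 under B6 and 337 under BALB/c hashtags, which goes against it, but keratin and Epcam RNA in those BALB/c droplets (2919 CPM, against 278 in weakly tagged ones) shows that such transcripts may come from epithelial cells in the same droplet. In the weakly tagged cells BALB/c-only transcripts stood at 8.34 CPM under NOD and 30.9 under BALB/c hashtags, with overlapping intervals. A hashtag too weak to place the cell had the values it needs only for weakly tagged cells (26 of 30 under NOD and 13 of 21 under B6 hashtags), with a median of 51.6% of hashtag UMIs on the leading hashtag over all NOD cells of the class against 94.2% in epithelial cells, while well-tagged cells still held 5899.9 CPM of H2-Ea under B6 (8 cells) and 3817 under NOD hashtags (4 cells). A difference between the strains in their leukocytes stays open and was not tested.

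Pseudogene models were among the largest differences between strains. Reads shared with a parent gene would lower the parent where the pseudogene is higher, and 19.0% of parents (4 of 21) were lower in NOD than in B6 (exact sign test p = 0.00720), under the bound set beforehand. That bound was ill-chosen, because 16 of the 21 parents are ribosomal protein genes, 15 of which were higher, as were 77 of all 84 ribosomal protein genes tested. In the class-adjusted fit 5 of 8 parents (62.5%) were lower in NOD (exact sign test p = 0.727), and in BALB/c 4 of 5 were lower over all cells and 3 of 4 in that fit. In epithelial cells alone 4 of 22 parents (18.2%) were lower in NOD (exact sign test p = 0.00434) and 3 of 8 (37.5%) in BALB/c (exact sign test p = 0.727). The fits thus differ, and shared reads cannot be told apart from a strain difference. Variants that lower the match to the B6 reference stay open as a general cause, because the scaling centres the changes and so sets the share of lower calls (53.1% in BALB/c) near even. Such variants in the pseudogene models themselves stay open as well. Of called models 17.9% were lower in NOD (interval 6.06% to 36.9%), which alone would go against them. But 16 of the 23 models called higher have ribosomal symbols, like most of the parents above, so that share cannot decide it. Strain-specific gene copies may contribute, which was not tested.

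Microfold-like cells were found almost only in B6. A barcode counted as marked when at least 9 of the 10 microfold markers were detected, a cut set on the cluster's own cells. If microfold-like cells of BALB/c and NOD had been lost among barcodes without a single hashtag, most marked ones would be BALB/c or NOD. Of 9 that could be placed 2 were (22.2%, interval 2.81% to 60.01%), too few to decide alone. With all 10 marked barcodes added to BALB/c and NOD their share would be 1.14%, under the lower limit of 6.10% for B6. Barcodes with fewer markers, such as shallow ones, were not counted, so this limit covers marked barcodes only. Microfold-like cells under B6 hashtags were weakly tagged, with a median of 960.5 hashtag UMIs against 2857 in all epithelial cells under B6 hashtags. With the genes called between strains in the class-adjusted fit left out before clustering, the B6 share was still 24.1 times the higher of the other strains (8.30% against 0.344%). That fit held no microfold-like sums, so strain genes particular to these cells could not be found and left out. The reclustering therefore cannot decide whether such genes define the cluster. A loss of marked barcodes is thus argued against as the whole cause. Loss of barcodes with fewer markers and strain genes particular to these cells stay open. A difference between strains in microfold-like cells, or in how the sort recovered them, may account for the pattern as a hypothesis.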

How the results depend on the processing

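Fits on epithelial cells alone, epithelial cells as the total, fits without the shallow cluster 5 and the tests within classes were chosen after the data were seen, and the cause of the changes below was not tested unless given. Of the 72 named results, all 72 kept their call and direction in the class-adjusted fit, which they had to pass by the naming rule, and with DESeq2, relative log expression and no gene filter. Epithelial cells alone kept 69, MULTIseqDemux and the margin rule 68 each, equal cells 62, and leaving out 1 mouse between 54 and 66. No named gene reversed. Over all alternatives 597 class tests were the same, 29 stronger, 33 weaker and 1 reversed, and 423 list tests were the same, 121 weaker and 6 reversed.

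For classes, resolution 0.5 called 3 between BALB/c and B6 (6 reported), because clusters 5, 8 and 10 had no match there, while the 27 class tests that could be compared were all the same. Myeloid or dendritic cell-like cells between NOD and BALB/c reversed with MULTIseqDemux (log2 -1.21). Without 1 mouse 5 to 7, 6 to 9 and 0 to 5 classes were called in BALB/c against B6, NOD against B6 and NOD against BALB/c, fewer mice being part of the cause. Cluster 8 had no match under the margin rule.

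For lists the class-adjusted fit called 6, 5 and 2 in the same order (16, 17 and 14 reported), camera with an estimated correlation 0, 0 and 0, and fry 10, 11 and 0. In the class-adjusted fit MHC class II (-1.56), Aire-stage (-0.471) and tuft markers (0.0315) reversed between NOD and B6, as did tuft markers (0.468) and tuft effectors (0.740) between NOD and BALB/c. Thymocyte markers reversed in epithelial cells alone (-0.11). These values are minus log10 of p, signed by direction. Without 1 mouse 14 to 19, 16 to 22 and 12 to 16 lists were called.

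For genes higher and lower between BALB/c and B6 (738 and 836), the class-adjusted fit called 275 and 213, equal cells 386 and 465, and no gene filter 1627 and 1887. Between NOD and B6 (1531 and 1588) the class-adjusted fit called 287 and 308, equal cells 847 and 1047, and no gene filter 2588 lower. Between NOD and BALB/c (966 and 834) MULTIseqDemux called 456 and 527, the class-adjusted fit 286 and 331, epithelial cells 591 and 539, equal cells 551 lower, and no gene filter 1739 and 1953. The class-adjusted fit tested fewer genes and equal cells used fewer cells. Without 1 mouse the counts ran from 158 to 696 and 170 to 825, from 537 to 1160 and 660 to 1138, and from 56 to 1024 and 43 to 799.

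Within cluster 8 (105 genes) DESeq2 called 37 and no gene filter 209, within enterocyte-hepatocyte-like cells (48) DESeq2 115, the margin rule 18 and no gene filter 590, and within tuft-like cells (2179) DESeq2 802. Without 1 mouse the counts ran from 91 to 172, 120 to 254 and 779 to 1609.

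The replicate numbers did not pair the mice, since deviations from the strain mean correlated at -0.0366, 0.0519 and 0.0379 between strains over 15888 genes. With the replicate block 1 class was called between NOD and BALB/c, 192 genes within cluster 8 and 97 within enterocyte-hepatocyte-like cells. The block ended the calls of cluster 8 between BALB/c and B6 and of cluster 8 and tuft-like cells between NOD and BALB/c. It called enterocyte-hepatocyte-like cells lower in BALB/c than in B6. Of the 72 named results it ended 6, Acta2 and Cxcl11 between BALB/c and B6, Cacna1c and Csn2 between NOD and B6, and Kcnip4 and Ranbp17 between NOD and BALB/c.

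H2-Ea over all cells, read as the label check, moved with the hashtag caller. With MULTIseqDemux it was 193 and 498 CPM in B6, 1113 in BALB/c 1 and 460.4 and 374 in NOD. The margin rule gave 455 and 798 in B6, 1125 and 1095 in BALB/c and 1096 and 1182 in NOD, and epithelial cells alone 39.4 and 72.4, 877 and 831, and 42.6 and 93.1. Not run were the planned test within classes, for which no epithelial class had the cells, and leaving out mice in the fit between classes, which gave no finite block correlation. The NOD mice, with 134 and 123 cells, limit what can be seen in rare classes.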

Other observations

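The tests reported here were chosen after the data were seen. Fits within further classes, at 10 or more cells per mouse, called 135 genes higher and 92 lower of 7310 between NOD and BALB/c in cluster 2, 48 and 55 of 8478 in proliferating-like cells and 212 and 108 of 9483 in tuft-like cells. Between BALB/c and B6 14 and 29 genes of 6219 were called in keratinocyte-like cells, and between NOD and B6 994 and 754 of 8312 in tuft-like cells. Tuft-like cells of NOD 1 and NOD 2 numbered 10 and 17. The taste-like tuft cluster 11, led by Rgs21 with Gnat3 among its leading genes, held 40% and 35.3% of them.

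In epithelial cells alone, 878 genes were higher and 1019 lower between BALB/c and B6, 1887 and 1792 between NOD and B6 and 591 and 539 between NOD and BALB/c, of 15348. Of these, 1455, 2807 and 938 were also called over all cells. With class in the model, epithelial cells gave 315 and 262, 439 and 438, and 386 and 393 of 8033.

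Strain-only transcripts found in both mice of a strain were Scg2, Skint3, Skint4, Skint9 and Trim12a for B6, Gm15772, Meg3 and Tmem181c-ps for BALB/c and Gm11942, Gm10263 and Rps24-ps3 for NOD. Scg2 is also a neuroendocrine marker and Meg3 a leading gene of the muscle-like cluster, so these follow class as well as strain.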
